A study of Drosophila melanogaster with 6 samples.

How the data were processed

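Whole-body RNA of Drosophila melanogaster L3 larvae was measured on 6 one-colour Agilent arrays, 3 of the control stock w1118 and 3 of larvae carrying DHR38Y214/Df(2)KetelRX32. Larvae were collected late in the preceding instar and left for 18 more hours at 25 °C on yeast paste, per the labels' protocols. The labels call the samples biological replicates. The labelling protocol describes a kit for both dyes, while each file held 1 channel and the labels name Cy3.

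The spots were read and background-corrected with Feature Extraction 9.5.1.1, per the file headers. The deposited scanner files give for each spot a processed signal, an intensity on a linear scale that is background-subtracted and detrended within its array and not normalized between arrays, with raw mean and background intensity beside it. Flags for outliers, saturation and signal well above background, which are other values of 0 or 1, come from the same software, per the file headers. The authors also deposited a table of log2 values per probe. Its 6 columns had a median of 9.12 each and shared quartiles, the pattern quantile normalization leaves, and they correlated with the scanner values of the same array at r from 0.959 to 1.00 across probes. The tool behind that table is not given in the sources used here, and its values entered as an alternative.

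From these files, log2 of the processed signal was taken on 43603 non-control spots per array, and each array's 75th percentile was subtracted. The mean percentile of 12.98 was added back, so levels read as normalised log2 signal. Spots flagged as outliers were left out (from 90 to 793 per array), and spots of a probe were averaged. A probe entered if it was well above background on all 3 arrays of at least 1 group with at least 2 values per group, which kept 21113 of 32162 probes. The probe with the highest mean signal stood for its gene, giving 15695 features, of which 10822 were named genes. Of all probes, 18121 were named by locus tag, 1246 by synonym, 220 by RefSeq transcript and 551 by the file alone, and 12024 carried no gene name. Names and the order of neighbouring genes came from a RefSeq table of release 6 of the genome. Coordinates are probe positions in dm3, per the file headers.

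The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no block. Errors of fold changes are limma's standard errors. A gene not well above background on any array of a group was given a bound: the mean of the bright group over the mean of, per array, the higher of the dimmest well-measured signal and the probe's own. With 3 arrays per group, an exact permutation test of a single gene cannot go below p = 0.1, and the number of arrays limits the precision.

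Gene lists, 26 in all, were fixed before the data were examined, and shifts were tested with camera (inter-gene correlation 0.01, adjusted over the lists), with an estimated correlation and with fry. Named genes followed a rule fixed at the same time: Hr38 and Fs(2)Ket, the 10 largest rises and 10 largest falls whose groups did not overlap, up to 4 members of each list past the threshold (with fewer than 2, the 2 brightest members), and called genes within 25 genes of the stretch from Hr38 to Fs(2)Ket. The text names a few of them and says where a gene outside the rule was added. Calls per chromosome arm were compared with Fisher's exact test.

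Each of 3 slides held 1 control and 1 mutant array of the same replicate number, so replicate and slide are 1 block. Same-numbered arrays deviated together from their group means across features (r = 0.178, 0.276 and 0.324), each over 0.1, so the numbers were taken to pair the samples. The main fit took no account of this pairing, and 2055 of its 2898 calls also passed with the block. Same-numbered arrays shared a slide, per the file headers, and slide and replicate number cannot be separated as the source. Control replicate 2 also correlated with mutant replicate 1 of another slide (0.297), above the same-numbered values of 0.178 and 0.276. Control replicate 3 had a net negative-control signal of 80.4 against 24.8 to 45.8 elsewhere, and 17362 probes well above background against 20999 to 25418.

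The comparison was tested on simulated data drawn from the means and SDs of 15471 features, with 200 genes changed. The fit recovered 26% of 50 genes changed 1.5-fold, 64% of those changed 2-fold, 74% at 4-fold and 94% at 16-fold, with 4 false calls among 133. The TCA cycle list, shifted by 0.4, was called, and 0 of the 25 other lists were. Draws from means and SDs carry no correlation between genes of a list. In the data the estimated correlation was 0.41 for that list and 0.29 for the immune list. The simulation therefore does not show how often camera calls lists of correlated genes falsely. Its shift of 0.4 also exceeded the medians of the lists called higher in the data (0.18 to 0.22), so finding shifts of that size was not tested. Alternatives covered normalization, background correction, the authors' values, the dim-probe filter, the probe rule, the variance prior, unmoderated variances, the block, array weights, the threshold and leaving out each array.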

Results

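The data were gene expression levels of whole L3 larvae on 6 arrays, with 3 control (w1118) and 3 mutant replicates. The mutant larvae combined an allele of Hr38, the single NR4A-type nuclear receptor of the fly, with a deficiency named after the gene Ketel. Between 17362 and 25418 of 32162 probes lay well above background per array. Control arrays correlated with each other at r from 0.986 to 0.994 across features. Mutant replicates 1 and 2 correlated at 0.989, and mutant replicate 3 correlated with them at 0.922 and 0.960. On mutant replicate 3, 1027 features lay over 2 log2 units below the control mean, 841 of them on no other mutant array.

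The comparison asked which transcripts differ between the mutant and the control stock. It cannot tell loss of Hr38 apart from other differences between the stocks, because stock and genotype split the arrays the same way. Hr38 itself was not well above background on any mutant array with any of its 5 probes. The part of Hr38 that either mutant chromosome alters is not given in the sources used here. The brightest probe of Hr38 (2L, 20683640 to 20683699, dm3) stood at 11.30 ± 0.36 in controls and 3.13 ± 0.43 in mutants (normalised log2 signal, SD, n = 3), at least 287-fold lower (adjusted p = 0.000151). That bound equals the fitted difference of -8.16, because the probe's own signal lay above the dimmest well-measured signal on each mutant array. It holds only for signal without normexp background correction, which put the difference at -5.28 on the log2 scale. The differences within slides 1 to 3 (-7.94, -8.32 and -8.22) rest on mutant signals that were not well above background, so they are no measured sizes. Genes just before Hr38 were also lower: Cen, which encodes a centrosomal protein, fell by 1.77 ± 0.14 (SE) on the log2 scale, and CG2608 fell by 0.84 ± 0.09 (not past the threshold when arrays were centred on medians, adjusted p = 0.214). Fs(2)Ket, which encodes an importin beta, rose by 0.60 ± 0.12 (adjusted p = 0.0238), a call lost without control replicate 2 or any single mutant replicate (adjusted p from 0.0652 to 0.0790), with no filter on dim probes (0.0712), with median centring (0.111) and without both arrays numbered 3 (0.108). Of 12 tested genes among the 25 before Hr38, 11 fell and 0 rose (median -1.11). The falls numbered 7 to 10 without a single array, 10 with the block and 3 with median centring. Of 17 tested genes among the 25 after Hr38, 2 fell and 3 rose (median 0.04). phr6-4, 15 genes before Hr38, was lower (adjusted p = 8.40e-05), but was well above background on 1 of 3 mutant arrays, so the size of its fall was not measured (-4.89 with normexp).

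**Figure D1:**
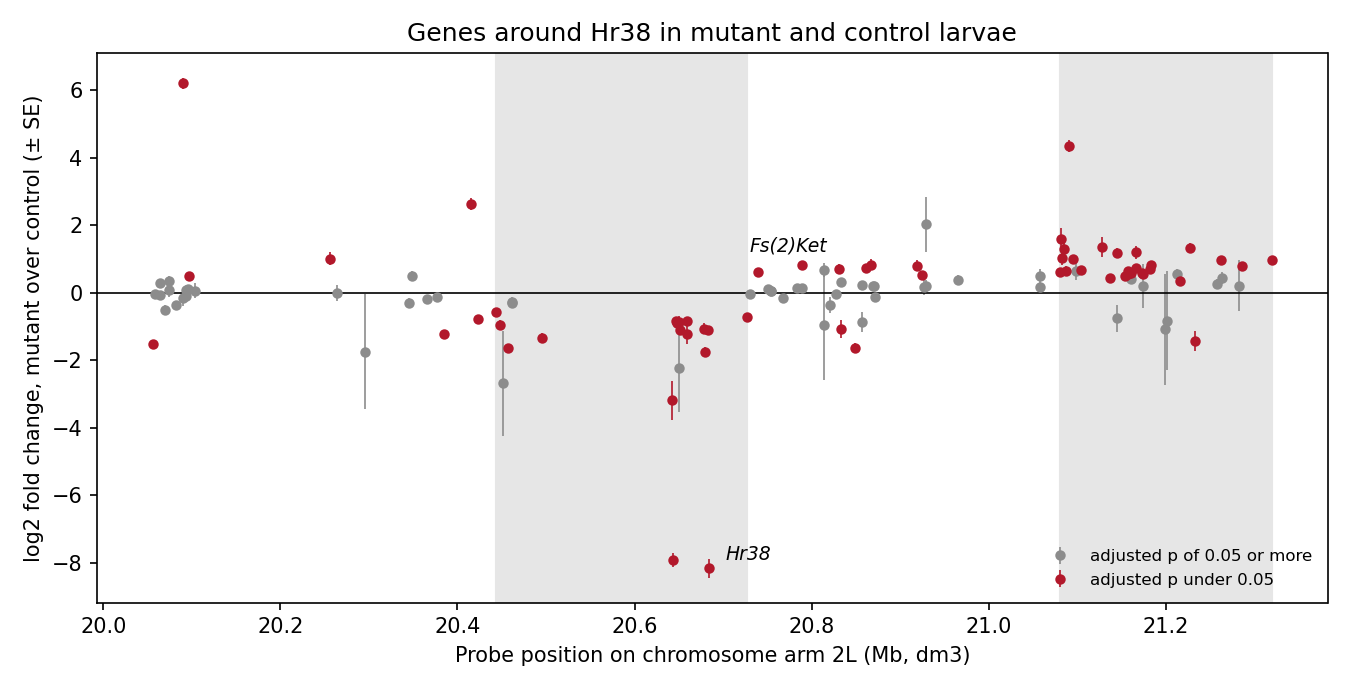
log2 fold change of mutant over control (± SE, 3 arrays per group) for tested genes along arm 2L, by probe position in Mb (dm3). Grey bands mark the stretches from CG31688 to CarT, which holds Hr38 and has a median of -1.09 over its 20 other tested genes, and from tadr to crc, with a median of 0.63 over 37.

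Across the genome, 2898 of 15695 features passed the threshold, 1465 higher and 1433 lower in the mutant, and 1983 of them were named genes. With the slide as a block the count was 2333 (1177 higher, 1156 lower), and 2055 features were called in both fits. The direction was the same on all 3 slides for 2874 calls. Among the largest rises were those of trypsin-type digestive proteases: epsilonTry rose by 12.87 ± 0.25 (a size resting in part on 1 control array not well above background, 11.65 with normexp) and betaTry, measured on 5 arrays, by 11.79 ± 0.34, while lambdaTry was not well above background in controls and was at least 5990.3-fold higher. The 10 largest rises with non-overlapping groups also held Prx3, CG3397, LSm7, CG11893 and mRF1, which are outside the protease list. Over the settings, Prx3 ran from 11.2 to 13.7, LSm7 from 8.95 to 12.5 and mRF1 from 6.18 to 9.88. Among the largest falls were Pig1, an intermoult gene of the salivary gland, at least 6179-fold lower, and the cuticle gene Cpr49Ad, at least 303-fold lower. Both of these bounds equal the fitted differences, because the probes' own mutant signals lay above the dimmest well-measured ones. With normexp the fitted differences of lambdaTry, Pig1 and Cpr49Ad were 10.15, -9.47 and -4.89, and that of lambdaTry without a single control ran from 11.88 to 13.64, so these bounds depended on the background correction. Changes of at least 4-fold numbered 236 rises and 167 falls. Of 11 genes changed at least 32-fold that had a further tested probe, 1 had a further probe under 2-fold. Non-overlapping groups were seen for 40.2% of features, where chance gives 10%. The count depended on single arrays and on scaling: 1127 without mutant replicate 2, 1685 without mutant replicate 3, 1930 without control replicate 1, 1298 without both arrays numbered 3, and 954 (605 higher, 349 lower) when arrays were centred on their medians, which moved the median change of all features by 0.19.

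Among carbohydrate genes, both alpha-amylase copies and 5 genes of glycogen and trehalose metabolism were lower in the mutant. The alpha-amylase copies fell, Amy-p from 16.85 ± 0.55 to 13.38 ± 0.95 (SD, n = 3; 11.1-fold, adjusted p = 0.0120) and Amy-d by 3.26 ± 0.53 (SE). These copies are close in sequence, so a probe may read both. Of 14 digestive carbohydrases, 3 fell, with Mal-B1 (-1.54 ± 0.27) besides these, and 0 rose (3 and 1 adjusted over the list alone, 3 and 1 with the block). Of 15 glycogen and trehalose genes, 5 fell and 3 rose. The falls were in Pgm1 (-0.72 ± 0.09), the trehalose transporter Tret1-1 (-0.69 ± 0.10), glycogen synthase Glys (-0.61 ± 0.10), glycogen phosphorylase Glyp (-0.43 ± 0.07) and CG9485, which encodes the glycogen debranching enzyme (-0.45 ± 0.07). The trehalose synthesis gene Tps1 rose by 0.49 ± 0.08, CG5171 by 0.60 ± 0.14 and CG5177 by 0.35 ± 0.08. Glyp, CG9485, Tps1 and CG5177 were chosen after their values were seen. With the block 5 fell and 1 rose, CG5171 (adjusted p = 0.0944) and CG5177 (0.0785) no longer passing. Neither list shifted against other genes (camera adjusted p = 0.209 and 0.728), while fry, which does not compare a list with other genes, gave the glycogen and trehalose list adjusted p = 0.0397, and the medians of the carbohydrases within slides were -1.17, -0.14 and -0.14. Centred on medians, Pgm1, Tret1-1, Glys, Glyp and CG9485 did not pass (adjusted p from 0.289 to 0.652), nor did Tps1 (0.207). Without both arrays numbered 3 none of these 6 passed (0.0550 to 0.111). Without mutant replicate 2, Tret1-1, Glys, Glyp, CG9485 and Tps1 did not pass (0.0576 to 0.0719), without mutant replicate 3 neither did the last 3 of these (0.0532 to 0.0614), Amy-d missed without control replicate 1 (0.0511), Mal-B1 without control replicate 1 or 2 or mutant replicate 2 (0.0565 to 0.0730), and CG5171 and CG5177 missed whichever single array was left out (0.0549 to 0.168).

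Hormone and fatty acid genes changed singly. AkhR, the receptor of the fly's glucagon-like hormone, rose by 2.52 ± 0.13 (adjusted p = 0.00045), foxo fell by 0.69 ± 0.07 and ImpL2, a secreted insulin antagonist, rose by 0.59 ± 0.11. The sugar sensor Mondo, which lies in the stretch from tadr to crc, rose by 0.79 ± 0.13. Centred on medians, foxo, ImpL2 and Mondo did not pass (adjusted p = 0.349, 0.150 and 0.107), and without mutant replicate 2 neither did Mondo (0.0633), while ImpL2 missed without control 1 or 2 or mutant 1 or 3 (0.0546 to 0.0662), with no filter on dim probes (0.0596), with the authors' values (0.0619) and without both arrays numbered 3 (0.0958). Of 26 insulin, TOR and energy hormone genes, 3 rose and 1 fell. Among 11 fatty acid oxidation genes, 2 rose and 1 fell: whd, which encodes the outer carnitine palmitoyltransferase, rose by 2.75 ± 0.21 and CROT by 1.11 ± 0.11, while CPT2 fell by 1.25 ± 0.13 (3 rose and 1 fell with the block). Of 20 glycolysis and gluconeogenesis genes, PCB rose (0.48 ± 0.12) and Ldh fell (-0.46 ± 0.12), with 0 called with the block (adjusted p = 0.0791 and 0.0748) or adjusted over the list alone. PCB missed when any array but control replicate 3 was left out (0.0911 to 0.168), and Ldh whichever single array was left out (0.0755 to 0.127). Of 21 lipid synthesis genes, 2 rose and 0 fell.

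Of 26 tested antimicrobial peptide, bomanin and other humoral immune genes, 11 fell, 1 rose and 14 did not pass (13 fell and 3 rose adjusted over the list alone). The list shifted down by camera (median -1.05, adjusted p = 0.00311), but not with an estimated correlation (adjusted p = 0.768). Its median ran from -1.95 to -0.83 over the alternatives. The antimicrobial peptide gene Mtk and the bomanin BomS1 were lower (adjusted p = 0.00317 and 0.00706), but were well above background on 1 mutant array, so the sizes were not measured (-4.90 and -4.96 with normexp). The bomanins BomS2 and BomS3 fell (-5.66 ± 0.54 and -5.07 ± 0.65), as did the diptericins DptA and DptB (-4.53 ± 0.57 and -4.17 ± 0.39). Without both arrays numbered 3, BomS1 and BomS3 did not pass (adjusted p = 0.0581 and 0.0511). PGRP-SC2, a peptidoglycan amidase, rose by 1.68 ± 0.17. DptA, DptB and PGRP-SC2 were chosen after their values were seen. With the block 9 fell and 1 rose (camera adjusted p = 0.00459), and the medians within slides were -2.14, -1.75 and -0.47. The stress-induced secreted factors TotA and TotC also fell (TotA from 18.45 ± 0.19 to 15.45 ± 0.55, SD, n = 3, and TotC by -3.25 ± 0.22, SE), although the other probe of TotC stood at 0.78 and its call was lost with the mean of its probes (-1.24, adjusted p = 0.112), among 4 falls and 3 rises in 21 heat shock and stress genes (4 and 2 with the block).

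**Figure D2:**
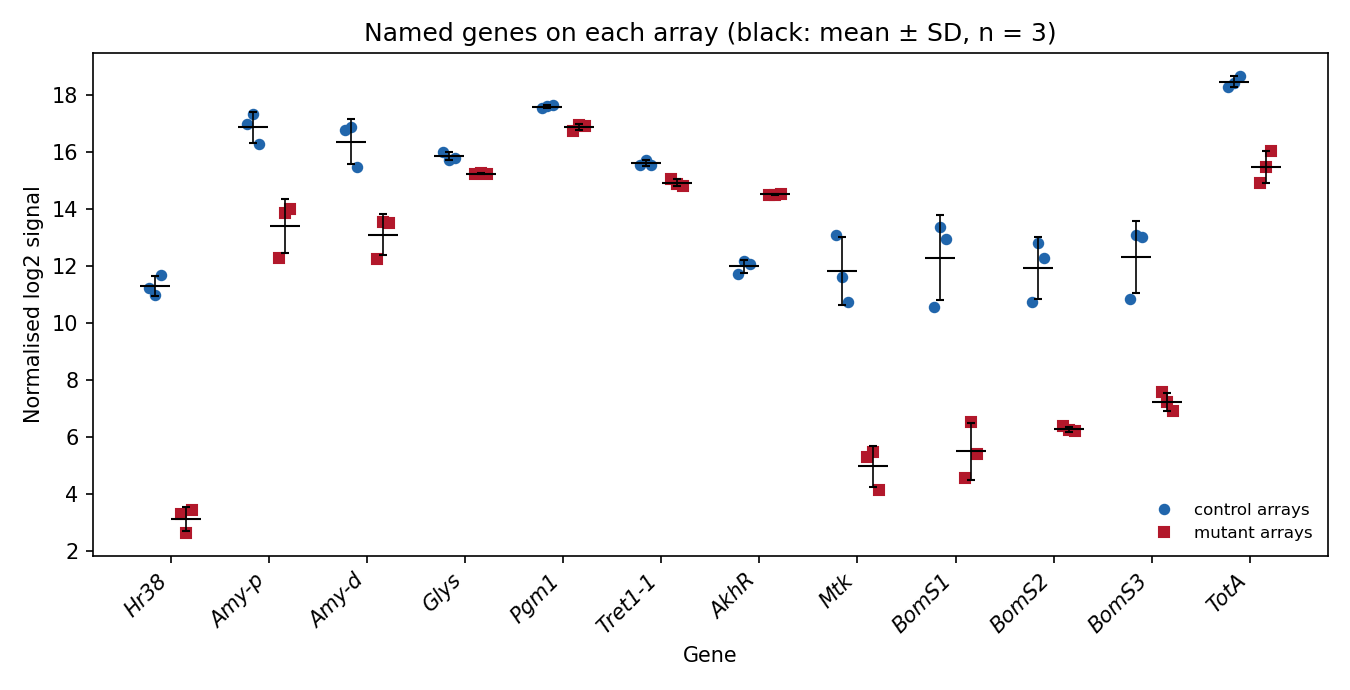
Normalised log2 signal of 12 named genes on each array, with controls as circles, mutants as squares and black marks for mean ± SD (n = 3). Amy-p averaged 16.85 in controls and 13.38 in mutants, and the values of AkhR were higher on all 3 mutant arrays.

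Detoxification and cuticle genes changed both ways. Of 81 detoxification genes, 18 rose and 8 fell (25 and 11 adjusted over the list alone, 18 and 7 with the block). The cytochrome P450 genes Cyp6a8 and Cyp6g1, the second of them known for insecticide resistance, rose by 7.26 ± 0.24 and 7.14 ± 0.42 (each well above background on 2 control arrays, 6.55 and 6.13 with normexp), and Cyp6a17 was at least 1019-fold higher (7.55 on the log2 scale with normexp, 9.29 to 11.11 without a single control). Other probes of Cyp6g1 ranged down to -0.56. Of 81 cuticle proteins, 7 rose and 22 fell (16 and 23 adjusted over the list alone, 10 and 20 with the block), with Lcp3 up by 4.26 ± 0.17. Of 16 pigmentation genes, 6 fell and 1 rose (6 and 2 adjusted over the list alone, 4 and 2 with the block), with yellow-d2 (well above background on 2 control arrays) up by 4.99 ± 0.25 (4.59 with normexp). Of 15 nuclear receptor genes, 1 rose and 2 fell. Hr96 rose by 1.63 ± 0.08, and EcR, the ecdysone receptor, fell from 14.22 ± 0.17 to 13.22 ± 0.11 (SD, n = 3), besides Hr38. Other probes of EcR ranged up to 0.51, and its call was lost with the mean of its probes (adjusted p = 0.339), with median centring (0.138) and without both arrays numbered 3 (0.0528).

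Ribosomal protein, midgut protease, muscle and TCA cycle genes shifted up slightly by camera when arrays were scaled to their 75th percentile. Of 92 cytoplasmic ribosomal protein genes, 8 rose and 1 fell (0 and 0 adjusted over the list alone, 3 and 0 with the block). That was a smaller share called than the 18.5% of all features. Of 30 midgut serine proteases, 7 rose and 0 fell (6 and 0 with the block). Of 23 muscle genes, 5 rose and 0 fell (3 and 0 with the block). Of 29 TCA cycle and respiratory chain genes, mAcon1, an aconitase that lies in the stretch from tadr to crc, rose by 0.56 ± 0.08 (adjusted p = 0.0531 without mutant replicate 2, 0.0522 under quantile normalization, 0.171 with median centring, 0.0750 with the authors' values and 0.0739 without both arrays numbered 3). The medians were 0.19, 0.22, 0.18 and 0.18 (camera adjusted p = 1.12e-06, 0.00311, 0.0167 and 0.00311), each with adjusted p = 0.768 with an estimated correlation. With the block these lists passed too (adjusted p = 3.6e-07, 0.00215, 0.00844 and 0.0012), and the lowest and highest medians within a slide, 0.10 and 0.30, were both those of the TCA cycle list. Under quantile normalization these shifts did not pass (adjusted p = 0.331, 0.266, 0.516 and 0.331), unlike that of the immune genes (0.00264). The same 4 lists were lost with the authors' values, and muscle and TCA cycle genes with median centring (adjusted p = 0.0611 each).

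Among the other lists, 1 of 18 ecdysone genes rose and 3 fell (1 and 4 adjusted over the list alone, 0 and 3 with the block), 2 of 7 salivary glue genes fell (1 rose and 1 fell with the block), 2 of 18 neuronal genes fell and 1 of 9 Malpighian tubule genes fell. LysP was at least 353-fold higher (6.26 on the log2 scale with normexp, 7.88 to 9.39 without a single control), the 1 rise among 7 lysozymes, and 1 of 20 DNA replication genes rose. Calls were 0 among 12 blood cell genes (1 fell with the block), 10 fat body and serum protein genes and 13 germline genes. They were also 0 among 3 genes of male dosage compensation (roX1, roX2 and msl-2). The dosage compensation genes had medians of -0.02, -1.43 and -2.11 within slides 1 to 3, and the germline genes 0.21, -0.18 and -0.60. Camera's adjusted p for the 21 lists not called ran from 0.0892 to 0.928. Median and mean differed in sign for glycogen and trehalose, lipid synthesis, lysozyme and heat shock genes (medians 0.09, 0.09, -0.14 and 0.08, means -0.16, -0.0042, 0.79 and -0.35, camera down, up, down and down), and each of these medians changed sign under at least 1 other setting. Counts adjusted over the list alone equalled those given where none is stated.

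By chromosome position, calls were more frequent on 2L (21.1% of 2635 features, odds ratio 1.24, adjusted p = 0.000251, Fisher's exact test) and 2R (20.1% of 2979, odds ratio 1.15, adjusted p = 0.0121). They were less frequent on X (14.5% of 2705 against 19.1% elsewhere, odds ratio 0.713, adjusted p = 3.07e-08). Changes of at least 4-fold were enriched on 2R (3.56% against 2.15%, odds ratio 1.68, adjusted p = 0.000115) and fewer on X (1.77% against 2.56%, odds ratio 0.687, adjusted p = 0.0469). Fisher's exact test takes genes as independent, but calls on 2L ran together in places. From CG31688 to CarT 17 of 21 genes with a RefSeq symbol fell, and from tadr to crc 26 of 37 rose and 1 fell. Part of the excess on 2L lies in these runs, and the p-values may be too small.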

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

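The numbers of calls moved with several choices, and leaving out both arrays numbered 3 and weights estimated gene by gene were chosen after seeing the data. Median centring gave 954 genes (605 higher, 349 lower), no filter on dim probes 1697 (729 higher), quantile normalization 931 lower, and adjusted p under 0.10 gave 2200 higher. Array weights gave 6282 (3354 higher, 2928 lower), but their estimate stopped before convergence with a weight of 50.4 on mutant replicate 2; estimated gene by gene, they gave 4595 (2451 higher). Without both arrays numbered 3 there were 1298 (635 higher, 663 lower). With the replicate block, which is the slide, there were 2333 (1177 higher, 1156 lower), Hr38 at -8.16 and 5 lists called. Besides the calls given above, that pairing changed no call of a list by camera or of a gene whose change was given in Results. Other genes of the naming rule lost their calls with the block, among them aurB (adjusted p = 0.0560), ng2 (0.0583), CG17470 (0.0520) and Mlp60A (0.0723). Leaving out single arrays gave 1127 to 2492 genes (514 to 1176 higher, 613 to 1316 lower), Hr38 from -8.33 to -7.92 and 5 to 7 lists. Of 26 lists camera called 5; it called 1 with quantile normalization or the authors' values and 0 with an estimated correlation. With fry 8 passed, which left out the TCA cycle list and took in detoxification, glycogen and trehalose, nuclear receptor and salivary glue genes. The nuclear receptor list holds Hr38, the mutated gene, and was not tested without it, so its pass shows nothing about the other receptors. Among features also called by the other setting, 7 turned direction with the mean of a gene's probes and 2 with probes well above background on all 6 arrays. Values of named genes and of lists that turned sign did not pass under that setting. Under quantile normalization these were Mdh1 (-0.041), Lsp1alpha (-0.026) and the fat body list (-0.042). With median centring they were vkg (0.071), tud (0.12), armi (0.16), LysD (0.055), LysS (0.15) and the lists for glycolysis (0.19), ecdysone (0.082), cuticle proteins (0.11), lysozymes (0.051), neuronal (0.0015) and germline genes (0.020). The authors' values turned RnrL (0.11) and the lists for glycogen (-0.17), lipid synthesis (-0.068) and fat body (-0.011). Probes well above background on all 6 arrays turned glycolysis (0.014), a setting that gave no value for Hr38; the mean of a gene's probes turned Mlp60A (-0.93), insulin signalling (-0.0045) and heat shock (-0.0026), and array weights turned LysD (0.016). Without both arrays numbered 3, RnrL (0.22), armi (0.015), glycolysis (0.0051) and heat shock (-0.0037) turned. Leaving out single arrays gave RnrL from -0.75 to 0.22, Lsp1alpha from -0.0068 to 0.25, armi from -0.16 to 0.058, glycolysis from -0.057 to 0.053, insulin signalling from -0.011 to 0.061, heat shock from -0.025 to 0.21 and germline genes from -0.49 to 0.058. Of the other comparisons of single genes and lists, 2281 kept side and direction, 371 lost a call and 28 gained one. Hr38 passed under every setting that gave it a value, from -8.60 to -5.28 (normexp background). Signal over background limits the dim genes, and control replicate 3 had the fewest probes above it. Leaving out arrays leaves fewer samples to the test. Median centring moved the median change of all features up by 0.19, and the medians of the lists it turned rose by about as much. Those turns follow the scaling and are no change of the lists against other genes. For the remaining settings the cause was not tested.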

Other observations

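The tests of males in the pool, loss of Hr38, array signal on features of like signal, stock chromosomes, the 25 genes before Hr38 and the other splits were chosen after the results were seen, and the stretches of 2L and the set of low transcripts were picked from these data.

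Past Hr38, with other genes between, a stretch of 2L ran higher in the mutant. From tadr to crc (2L, 21080919 to 21319450, dm3, 239 kb), 26 of 37 tested genes with a RefSeq symbol rose and 1 fell, with a median of 0.63 and medians within slides of 0.63, 0.75 and 0.64. Mondo and mAcon1 lay in it. From CG31688 to CarT (20443818 to 20727239, 283 kb), a stretch that holds Hr38 and ends 5 genes past it, 16 of the 20 other such genes fell and 0 rose, with a median of -1.09. Tested genes among the first 25 past Hr38 had a median of 0.04, and those 26 to 50 past it 0.22. Fs(2)Ket lay between the stretches and rose, although the deficiency carries its name.

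These runs may reflect gene copy number on the mutant chromosomes, as a hypothesis: 1 copy from CG31688 to CarT and 3 copies from tadr to crc. The tested genes among the 25 before Hr38 had a median of -1.11, which prompted the idea and does not test it. Features without a RefSeq symbol took no part in finding the runs: 4 in the lower stretch had a median of -1.23, and 16 in the higher stretch had a median of 0.66, where 6 rose and 0 fell. The ranges for these were set beforehand, but that for the lower stretch repeats the range written after the median of -1.11 was seen. Which features counted as without a symbol was corrected after the values were seen. These features lie inside the runs, so they show that the shifts extend to them and do not test copy number against another regional cause. A run as low was found in 0.626% of 4154 windows elsewhere on the second chromosome, or 1 of 347 separate windows (95% exact interval 0.0073% to 1.60%), and overlapping windows are not independent, so a stock difference along that chromosome cannot be told apart. No sequence or DNA copy number was measured here.

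Mutant replicate 3 lacked many transcripts that the other arrays carried. On it 1027 features lay more than 2 log2 units below the control mean, 841 of them on no other mutant array, against 207 and 196 on mutant replicates 1 and 2. CG32445 stood at 11.04 in controls and at 12.20, 10.75 and 3.61 on mutant replicates 1 to 3, an example picked after its values were seen. Loss of Hr38 as a shared drop was argued against by mutant replicates 1 and 2: their joint median over the set lay 0.14 from controls (SD over transcripts 1.59), as opposite medians of 0.89 and -0.61, against -4.51 on mutant replicate 3. A drop of all features of like signal was argued against by their median of -0.24. Those values were scaled to each array's 75th percentile, so they cannot show a uniformly dim array. Before scaling, that percentile was 13.13 on mutant replicate 3, within the range of 12.73 to 13.32 over the arrays. Its median signal of 710 was the lowest, against 758 to 1120 elsewhere. The odds ratio of X in the set (1.08, 95% interval 0.910 to 1.27) decided nothing about a dim array. Fewer males in that pool may be a candidate source: the male RNAs roX1 and roX2 averaged 1.24 log2 units below the lowest other array, itself a mutant array. On mutant replicate 3 roX1 stood at 13.21 against a control mean of 15.71, and roX2 at 9.49 against 12.54. Both falls were smaller than the median of -4.51 over the set, so this candidate is not shown to account for the whole drop. The sex of the larvae was not given in the labels.

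Calls of at least 32-fold numbered 60 rises and 28 falls. A sequence difference at the probe may account for some, but 1 of 11 such genes with a further tested probe had a further probe that changed under 2-fold (9.09%), against 8 of 47 among calls of 4-fold to 32-fold (Fisher's exact p = 1), too few to decide. Different chromosomes in the stocks cannot be told apart from loss of Hr38, because stock and genotype split the arrays the same way. The odds ratio of X over all calls (0.713) decided nothing here, and for calls of at least 32-fold it was 0.718 (95% interval 0.343 to 1.37, adjusted p = 0.489).

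The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05, and 1 split, the real one, gave 2898 genes. The highest of the other splits gave 0 with limma (1791 at an unadjusted p under 0.05, against 5303). Of the splits that part all 3 pairs, the others gave at most 147 at that level. Each other split mixed control and mutant arrays within both groups, so the difference between stocks widened its spread. The counts of the other splits are therefore no measure of what chance gives.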
